A study of Mus musculus with 6 samples.

How the data were processed

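RNA sequencing was done on ureteric bud (UB) lineage cells, the epithelium that branches to form the collecting system of the kidney. Cells were sorted by fluorescence from mouse embryos at embryonic stage E16.5. Each genotype was represented by 3 libraries, which the labels number as biological replicates. The control embryos carried a Hoxb7-driven Cre-GFP transgene and 1 floxed Ash2l allele (Ash2l F/+). The conditional knockout (cKO) embryos carried the same transgene and both alleles floxed (Ash2l F/F). The labels do not say whether a replicate is 1 embryo or a pool, nor whether replicates share a litter or a sequencing day. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a strand-preserving mRNA kit.

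The authors deposited a table of raw read counts per gene and a table of FPKM values, each with a column for every library. HISAT2, HTSeq, Cufflinks, DESeq and the build GRCm39 are named in the submitters' processing notes, without versions or roles. The strand setting of the counting is not given in the sources used here, so reads of a gene and of an overlapping antisense gene may not have been kept apart. Both tables list 17189 genes with Entrez Gene identifiers, and the lowest total over the 6 libraries is 1 count. Deposited FPKM values were checked against the counts. They equal the counts divided by 1 length per gene and 1 factor per library, with a largest relative deviation of 2.54e-07. FPKM is therefore a rescaling of the counts and not an independent measurement. The gene table in the reference is of another build, so it was used for gene names only: 17094 of the identifiers matched, and no coordinates are given. Which exons of Ash2l are floxed is not given in the sources used here.

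Library totals ranged from 9620235 to 10538314 counts. The floor used for a gene listed at 0 is 3 counts, which is 0.285 to 0.312 CPM (counts scaled to library size) in a single library. Such floors cover counting error only, because PCR copies are not independent molecules. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom between 10.5 and 79.3), so no pair was treated as 1 library deposited more than once. This does not show that the libraries come from separate embryos, and p-values measure the spread between these libraries.

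The cKO libraries were compared with the control libraries with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 13047, and library sizes were scaled with TMM factors. The robust quasi-likelihood F-test was used with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called to have risen or fallen in cKO at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM values are given as mean ± SD over n = 3 libraries, scaled by the TMM factors. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Adjustment was over the 24 of 28 lists with at least 5 tested members. Each was tested again with a correlation estimated from the data. That version takes its degrees of freedom from the few libraries and not from the genes, so it can call far less. A call lost with it does not show that correlation between genes made the call. GO and KEGG terms given in the deposited tables with 15 to 300 tested genes were tested in the same way. The lists were also tested with fry in limma, planned beside camera. It asks whether the members changed at all, and not whether they changed more than other genes. Its p-values are not adjusted over lists and are given for some lists only. The lists were fixed before the data were examined. Synonyms were used to find list members only where the symbol was not the current name of another gene.

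Genes named in the text followed a rule also fixed before the data were examined. It takes Ash2l and 8 genes of the RET pathway and the ureteric tip whatever their values. It also takes the 6 largest rises and the 6 largest falls among called genes with a mean log2 CPM of at least 2, every cKO library on the same side of every control library, and a symbol that is not a predicted model. From each list it takes the 2 members with the smallest p, or 1 for lists of other cell types and technical lists, and from the 4 annotation terms with the smallest p, skipping a term that shares most of its members with an earlier one, the 2 members with the smallest p. Any other gene named was chosen after its values were seen.

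The steps were tested on simulated counts, drawn for the real genes from the control means, library sizes and fitted dispersions, with 200 genes changed. With 6 libraries over 13047 genes, 17% of genes changed 2-fold and 42.9% of genes changed 4-fold were called, and 6.35% of the calls fell on unchanged genes. Without cKO replicate 3, over 13660 genes, 69% and 95% were called, and 12.3% of the calls fell on unchanged genes. Each setting was drawn once. The simulated cKO replicate 3 does not lack genes as the real library does. The share of false calls also depends on how many genes change. These percentages therefore describe the simulation and are not the error or recovery of the real calls.

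Alternatives fixed in advance were other library scalings, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, thresholds of a 2-fold change and of an adjusted p of 0.01, each library left out in turn, and camera with an estimated correlation or without genes shared between lists. Added after the data were seen were limma-voom with a quality weight for each library, the main test without the genes missing in cKO replicate 3, and the replicate block without that library. Tables and figures were made with Python 3.11.15 and matplotlib 3.10.9. No sample was left out of the main comparison. Xist and the mitochondrially encoded genes were not analysed here. Some genes that the rule takes are not reported here.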

Results

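The transcriptomes of sorted UB cells were compared between 3 control and 3 Ash2l cKO samples at E16.5. ASH2L is a core subunit of the complexes that methylate histone H3 at lysine 4, a mark of active promoters. The series asks how its loss alters the branching epithelium, with attention to signalling by the receptor RET and its co-receptor GFRA1. Control replicates 1, 2 and 3 had 10359475, 10538314 and 10510585 counts. The cKO replicates had 9860475, 9620235 and 9810855 counts.

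Ash2l (Entrez Gene 23808) had 1933, 1853 and 1624 counts in control replicates 1, 2 and 3, and 451, 292 and 214 counts in cKO replicates 1, 2 and 3. Its level was 175 ± 15.6 CPM in controls and 32.4 ± 12.6 CPM in cKO (SD, n = 3 each). The log2 fold change was -2.44 (SE 0.284, edgeR adjusted p = 0.00786), and all cKO libraries were below all control libraries. The floxed exons are not given in the sources used here, so counts from outside them can remain in cKO, and the fold is relative to controls that carried Cre and 1 floxed allele. Without any single library the call remained, with a highest adjusted p of 0.0493 without control replicate 1. The call was lost with the replicate number as a block. Among the 22 tested subunits of H3K4 methyltransferase complexes, Ash2l alone was called in the 6 libraries. Without cKO replicate 3, Men1, which encodes the MLL-associated protein menin (log2 fold change -0.34, adjusted p = 0.0374), and Pagr1a (-0.52, adjusted p = 0.0288) fell as well. The list as a whole was not called (camera adjusted p = 0.451), and adjusted over the list alone 1 member fell. By fry, with the targeted gene Ash2l among the members, the unadjusted p was 0.00619, down (0.0138 without cKO replicate 3).

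Over the 13047 genes tested, 459 rose and 469 fell in cKO cells. With a change of at least 2-fold these numbers were 312 and 264. The 6 largest fitted rises and falls are given for called genes with a mean log2 CPM of at least 2 over all libraries. Every cKO library had to lie on the same side of every control. Genes below that mean had larger fitted changes. Slc4a9 and Ddx3y were among these, at 38 and 77.1 CPM in controls and at or near 0 in cKO, which lowers the mean. Actc1, cardiac alpha-actin, rose from 0.292 ± 0.353 to 49.2 ± 26.2 CPM. Krt17, a keratin induced in stressed epithelia, rose from 0.708 ± 0.382 to 81.4 ± 34.5 CPM, and Cnn1, the smooth muscle protein calponin, from 0.452 ± 0.245 to 48.0 ± 26.0 CPM (log2 fold changes 6.82, SE 0.592, and 6.69, SE 0.661). Ankrd1, a cardiac ankyrin repeat protein, rose with a log2 fold change of 5.82 (SE 0.641), Gpha2, a glycoprotein hormone subunit, with 5.89 (SE 1.11), and Ppbp, a platelet chemokine, with 5.74 (SE 0.917). The 6 falls under these limits were those of Foxi1 (-6.63, SE 1.02), Scara3 (-5.14, SE 0.617), Pimreg (-3.32, SE 0.556), Grb10 (-3.21, SE 0.344), Tmem221 (-3.01, SE 0.288) and Gstt1, a glutathione transferase (-2.96, SE 0.280). The calls of Actc1 (adjusted p = 0.0729), Gpha2 (0.144), Ppbp (0.101) and Foxi1 (0.099) were lost without control replicate 2, that of Scara3 (0.0564) without control replicate 3 and that of Pimreg (0.0957) without control replicate 1. The other 6 of these genes kept their calls without each library in turn. Of those that lost theirs, Gpha2 was called in 1 of 6 such tests, Foxi1, Pimreg and Ppbp in 2, Actc1 in 4 and Scara3 in 5. All of them were called without cKO replicate 3, with a highest edgeR adjusted p of 0.0306 for Ppbp.

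One library stood apart from the other 5. In cKO replicate 3, 1453 of the 11738 genes with more than 10 counts in each other library were listed at 0 (12.4%), against at most 3 genes in any other library by the same measure. Its log2 CPM correlated with the other libraries at 0.868 to 0.896, while the other libraries correlated at 0.983 to 0.989 within a group and 0.951 to 0.955 between groups. These correlations are across genes, which are not independent replicates. Without this library 1865 genes rose and 2032 fell among 13660 tested. In the simulation of this setting 12.3% of the calls fell on unchanged genes. Of the 928 genes called with all 6 libraries, 924 were called without it and none had the opposite sign. Leaving out control replicate 1, 2 or 3 left 159, 177 or 121 calls, and leaving out cKO replicate 1 or 2 left 443 or 240. Of 48 named genes that were called, 18 kept the call without each library in turn and 30 lost it without at least 1 library. Of 87 other called members of gene lists, 9 kept the call and 78 lost it in this way. Only 2 of the 87 lost it without cKO replicate 3. Among those named below, Mmp14, Spry2, Dusp6, Aqp3, Kcnj1, Hoxd1, Bmp4 and Notum were each called in 1 of these 6 tests. The same held for Cdh2, Acta2, Itga3, Irf7, Cxcl10, Ldha, Jag1 and Atf3. For all of these genes except Atf3, that 1 test was the one without cKO replicate 3. Where a lost call is given for a gene in what follows, its adjusted p is the highest over the libraries left out, and the call can also be lost without others. Such a loss does not by itself show that the call rests on the library named. Leaving out any library but cKO replicate 3 lowered the number of calls. Libraries also differed in Y-linked reads. Ddx3y, Uty and Kdm5d had reads in each control and none in any cKO library. Eif2s3y had 736, 815 and 439 counts in control replicates 1, 2 and 3, none in cKO replicates 1 and 2, and 504 in cKO replicate 3. Reads of Ddx3y, Uty and Kdm5d therefore go with the genotype in all 6 libraries, and reads of Eif2s3y in 5 of the 6. The comparison between groups cannot separate Y-linked reads from genotype.

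**Figure D1:**
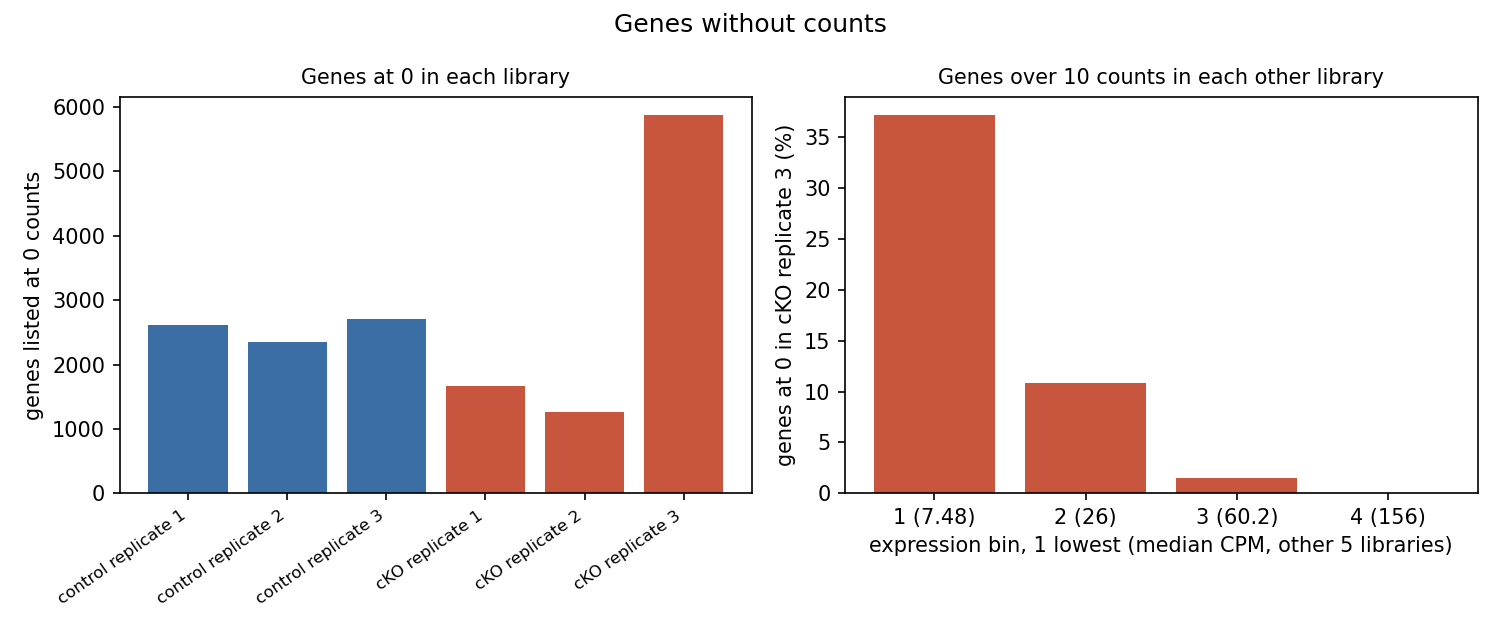
Left, number of genes listed at 0 counts in each library, control in blue and cKO in red. Right, percent of genes at 0 in cKO replicate 3 among genes with over 10 counts in each of the other 5 libraries, in 4 equal bins of mean expression with the median CPM in parentheses; cKO replicate 3 has 5871 genes at 0, and the percent falls from 37.1 in the lowest bin to 0.0681 in the highest.

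Genes of the RET/GFRA1 pathway moved in both directions. Of 23 tested members, 5 fell and 2 rose; adjusted over the list alone, 6 fell and 2 rose, and without cKO replicate 3, 8 fell and 3 rose. Wnt11, a ligand made at the ureteric tip under RET control, fell from 1229 ± 81.5 to 386.3 ± 38.2 CPM (log2 fold change -1.67, SE 0.105, edgeR adjusted p = 0.00341). Gfra1 (Entrez Gene 14585) fell from 935 ± 94.4 to 471 ± 87.2 CPM (-0.99, SE 0.157, adjusted p = 0.0176). Etv5, an ETS factor downstream of RET, fell by 0.81 on the log2 scale (SE 0.135, adjusted p = 0.0203). Grb10, an adaptor that binds receptor tyrosine kinases, fell from 468 ± 37.4 to 50.7 ± 24.8 CPM (adjusted p = 0.00644), and the matrix metalloproteinase gene Mmp14 fell by 1.61 (SE 0.292). Both called feedback inhibitors of this pathway, Spry2 (0.61, SE 0.135) and Dusp6 (0.60, SE 0.137), rose. Ret itself (Entrez Gene 19713) was 635 ± 114 CPM in controls and 294 ± 103 CPM in cKO, below every control in every cKO library, but its adjusted p was 0.0666. Ret fell by 0.86 without cKO replicate 3 (SE 0.138, adjusted p = 0.000497). Etv4 (-0.53, SE 0.276), Sox9 (-0.31, SE 0.180), Spry1 (0.14, SE 0.125) and Cxcr4 (-0.07, SE 0.891) were not called; Cxcr4 had 124 counts in cKO replicate 3 against 17 and 23 in the other cKO libraries, and it fell by 1.5 when that library was left out (SE 0.509, adjusted p = 0.0408). The list was not called by camera (adjusted p = 0.155). By fry its unadjusted p was 0.0417, down, and 0.0577 without cKO replicate 3. With 1 library left out at a time, Gfra1 was called in 2 and Etv5 in 1 of 6 tests, with a highest adjusted p of 0.0863 (without control replicate 3) and 0.0774 (without control replicate 2). Spry2, Dusp6 and Mmp14 were each called in 1 of 6 of these tests. Their highest edgeR adjusted p was 0.184 and 0.192 without control replicate 2, and 0.115 without control replicate 3.

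Among 16 tested ureteric tip markers, 3 fell (Wnt11, Gfra1 and Etv5) and Tmem59l rose (0.97, SE 0.162); adjusted over the list alone, 4 fell and 1 rose. The list was not called with 6 libraries (camera adjusted p = 0.135). Its unadjusted fry p was 0.0231, down, and 0.0302 without cKO replicate 3. Without cKO replicate 3, 7 members fell and 2 rose, and the list was called down (adjusted p = 0.0405, and adjusted p = 0.754 with an estimated correlation); with library weights it was called too (0.0452). Of 19 genes of ERK feedback and output, 5 rose and 1 fell; adjusted over the list alone, 7 rose and 1 fell, and without cKO replicate 3, 7 rose and 1 fell. Phlda1 (1.69, SE 0.284), Dusp5 (1.77, SE 0.378) and Ccnd1, which encodes cyclin D1 (0.55, SE 0.0874, edgeR adjusted p = 0.0174), rose. Etv5 was the member that fell. This list was not called either (camera adjusted p = 0.123), but it was called up with limma-voom (0.0365), with library weights (0.031) and without members shared with other lists (0.0357). With all 6 libraries its adjusted p = 0.659 with an estimated correlation, and its unadjusted fry p was 0.22. The call of Ccnd1 was lost without control replicate 2 (adjusted p = 0.101), and that of Dusp5 without each library in turn (0.158 without control replicate 2, 0.0859 without cKO replicate 3).

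**Figure D2:**
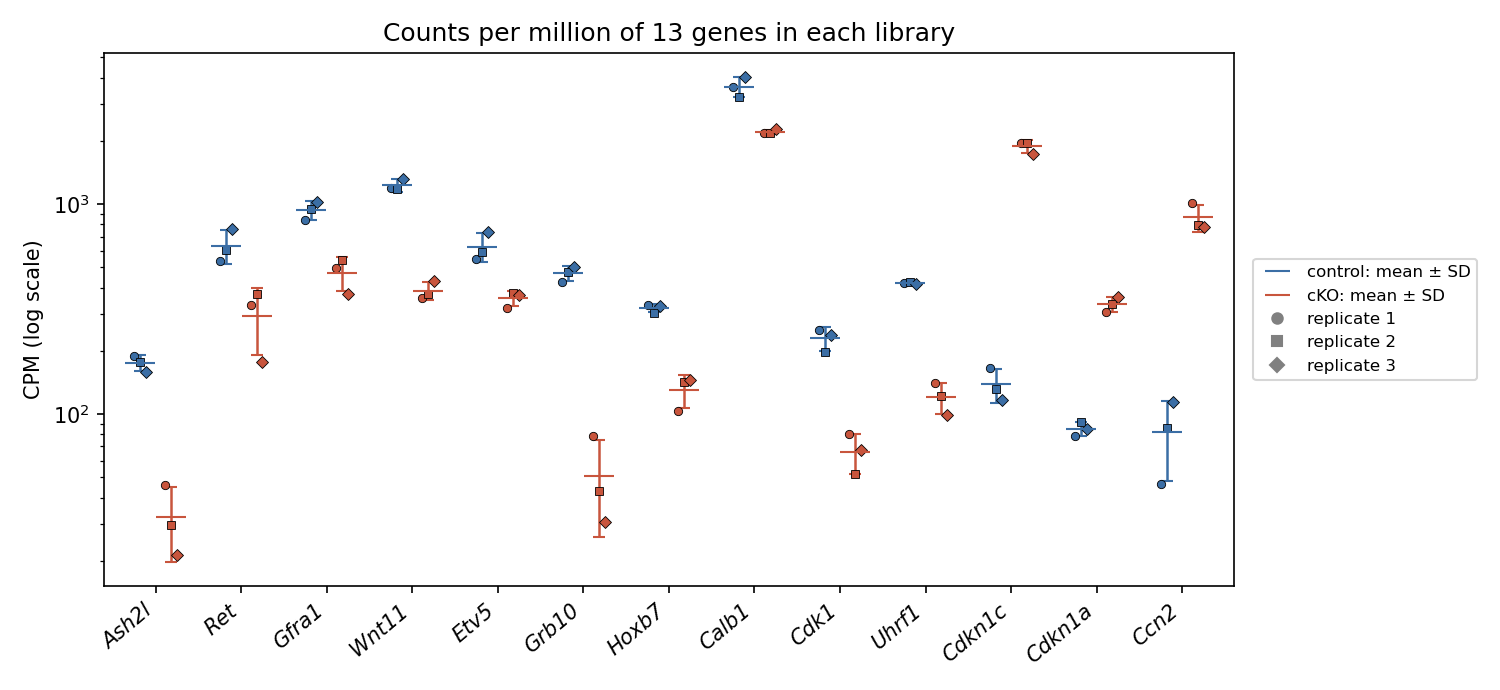
CPM on a log axis for genes named in the text, control in blue and cKO in red; symbols mark replicates 1, 2 and 3, and bars are mean ± SD of 3 libraries. Ash2l, Gfra1 and Wnt11 lie lower in all cKO libraries than in all controls, and Cdkn1c and Cdkn1a lie higher.

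The list of genes that mark the ureteric epithelium was called down. Of 20 tested, 5 fell, none rose and 15 were not called; adjusted over the list alone, 7 fell, and without cKO replicate 3, 10 fell. Hoxb7, whose promoter drives the transgene, fell from 321 ± 14.8 to 130.3 ± 23.8 CPM (log2 fold change -1.30, SE 0.151, edgeR adjusted p = 0.00784). Calb1, the calcium-binding protein calbindin, fell by 0.71 (SE 0.0964, adjusted p = 0.0114). Gata3, a transcription factor of the duct lineage, fell by 0.76 (SE 0.148), and Epcam, an epithelial adhesion molecule, by 0.61 (SE 0.0983). The list median was -0.58, and the camera adjusted p was 0.000487, against an adjusted p = 0.218 with an estimated correlation. In the same libraries the markers of nephron epithelium and podocytes, other cell types, were called up (median 1.19, camera adjusted p = 0.0052; adjusted p = 0.218 with an estimated correlation). Their median was 0.69 without cKO replicate 2 and 0.74 without control replicate 1, where the call was lost (0.0565). The calls of Hoxb7 and Calb1 were lost without control replicate 3 (adjusted p = 0.0529) and without cKO replicate 2 (adjusted p = 0.0603).

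Both lists of differentiated collecting duct cells were called down, with few members called. Of 11 tested intercalated cell genes, 2 fell and none rose, all 11 had a negative fold change, and the median was -3.03 (camera adjusted p = 3.65e-05; adjusted p = 0.262 with an estimated correlation). The median was -0.92 over the 9 genes left by the stricter filter, -2.0 without the genes missing in cKO replicate 3, and -1.19 on the log2(FPKM + 1) scale, which understates the change of low genes (-0.67 without a filter). Foxi1, the master regulator of acid-base transporting intercalated cells, fell from 98.6 ± 40.8 to 0.982 ± 1.36 CPM (edgeR adjusted p = 0.0159). Slc4a9, an anion exchanger of these cells, had 318, 536 and 325 counts in controls and 0, 4 and 0 in cKO (adjusted p = 0.0112). Adjusted over the list alone 2 fell, and without cKO replicate 3, 8 of 14 fell. Of 19 principal cell genes, 3 fell and 1 rose; adjusted over the list alone, 7 fell and 2 rose, and without cKO replicate 3, 9 fell and 3 rose. Scnn1g, a subunit of the epithelial sodium channel, fell by 1.45 (SE 0.221), Hsd11b2, which inactivates glucocorticoids, by 1.71 (SE 0.280), and the water channel gene Aqp3 by 2.00 (SE 0.395). Kcnj1, a potassium channel gene, was at 0 in all controls and at least 97.9-fold higher in cKO, with the floor of 3 counts taken over the group. With 1 library left out at a time it was called in 1 of 6 tests (highest edgeR adjusted p 0.103, without control replicate 3). The principal cell list was called down (camera adjusted p = 0.0326; adjusted p = 0.578 with an estimated correlation), and this call was lost without control replicate 2 (0.0504) and without cKO replicate 2 (0.15). Its median of -0.79 was -0.45 on the log2(FPKM + 1) scale and -0.44 there without a filter. Without control replicate 2, adjusted p was 0.099 for Foxi1, 0.0783 for Slc4a9 and 0.0901 for Hsd11b2, and without cKO replicate 2 it was 0.0692 for Scnn1g.

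Of 9 tested urothelial genes, 2 fell: the uroplakin genes Upk3a (-2.63, SE 0.318, edgeR adjusted p = 0.00846) and Upk1b (-2.01, SE 0.314, adjusted p = 0.0172). Adjusted over the list alone 2 fell, and without cKO replicate 3, 4 fell and 3 rose. The rises without that library were those of Trp63, a regulator of basal cells (2.19), Krt20 (2.24) and Upk3b (0.78). The list was called down with 6 libraries (camera adjusted p = 0.0406; adjusted p = 0.262 with an estimated correlation), and the call was lost without each library in turn, with adjusted p between 0.0576 without control replicate 3 and 0.363 without cKO replicate 3. It was also lost with log2(FPKM + 1) (0.0745), log2(FPKM + 0.1) (0.0614) and library weights (0.141). The calls of Upk3a and Upk1b were lost without control replicate 3 (adjusted p = 0.0529) and without control replicate 1 (adjusted p = 0.0774).

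Both cell cycle lists were called down. All 30 G2/M genes had a negative fold change, 20 fell and none rose, with a median of -1.71 (camera adjusted p = 3.4e-14; adjusted p = 0.218 with an estimated correlation). Adjusted over the list alone 24 fell, and without cKO replicate 3 all 30 fell. Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell from 230.5 ± 24.5 to 48.8 ± 12.7 CPM (edgeR adjusted p = 0.0057). Cdk1, the mitotic kinase, fell from 229.5 ± 28.9 to 66.1 ± 14.2 CPM (adjusted p = 0.00644), and Mki67 fell by 1.52 (SE 0.196). All 30 G1/S genes also had a negative fold change, 17 fell and none rose, with a median of -1.11 (camera adjusted p = 1.37e-12; adjusted p = 0.262 with an estimated correlation). Adjusted over the list alone 23 fell, and without cKO replicate 3, 26 fell. Uhrf1, which recruits DNA methylation to replicated DNA, fell from 421.5 ± 5.28 to 120.4 ± 20.4 CPM (adjusted p = 0.00409), and the helicase gene Hells fell by 1.25 (SE 0.128). Uhrf1, Hells, Ube2c and Cdk1 kept their calls without each library in turn.

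Annotation terms called down were mostly of chromosome segregation and DNA replication. Of 2362 terms tested, 18 were called down and 4 up with camera, 0 were called with an estimated correlation, and 34 were called without cKO replicate 3. Mitotic sister chromatid segregation had 12 of 30 genes that fell and none that rose (median -0.93, camera adjusted p = 1.94e-06; adjusted p = 1 with an estimated correlation). The terms called up were hormone activity (10 of 31 genes rose, camera adjusted p = 0.0125; 0.211 without cKO replicate 3), insulin-like growth factor binding (0.0229; 0.106 without it), complement and coagulation cascades (0.0333) and negative regulation of peptidase activity (0.0372); the adjusted p was 1 for each with an estimated correlation. Non-canonical Wnt signalling was called down (3 of 21 genes fell, camera adjusted p = 0.00762; adjusted p = 1 with an estimated correlation). Leading members of mitotic sister chromatid segregation were Cenpk (-1.31, SE 0.156), a kinetochore protein, and Mad2l1 (-1.49, SE 0.184), of the spindle checkpoint. The centromeric region of the chromosome had 34 of 142 genes that fell and 2 that rose (camera adjusted p = 5.41e-06), led by Pmf1 (-1.25, SE 0.113) and Hells. DNA replication in KEGG had 8 of 35 genes that fell (camera adjusted p = 3.78e-05) and DNA replication initiation 7 of 20 (0.000543); Mcm2 (-1.07, SE 0.117) and Mcm3 (-1.15, SE 0.144), subunits of the replicative helicase, led both. The adjusted p was 1 for each of these terms with an estimated correlation. Without control replicate 3 the edgeR adjusted p was 0.0612 for Cenpk, 0.0559 for Mad2l1 and 0.0582 for Mcm3.

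The list of p53 targets and inhibitors of cyclin-dependent kinases was called up. Of 23 tested, 13 rose and none fell; adjusted over the list alone 14 rose, and without cKO replicate 3, 15 rose and 1 fell, Sesn1. Cdkn1c, the imprinted inhibitor p57, rose from 138 ± 25.5 to 1887 ± 130 CPM (log2 fold change 3.77, SE 0.158, edgeR adjusted p = 0.00118). Cdkn1a, the p53 target p21, rose from 84.9 ± 6.70 to 334 ± 28.5 CPM (1.98, SE 0.114, adjusted p = 0.00311). Ccng1 (1.75, SE 0.144), Gdf15, a stress-induced cytokine (3.42, SE 0.469), and Bax, an effector of apoptosis (0.79, SE 0.119), rose too. The list median was 1.31, and 0.84 on the log2(FPKM + 1) scale. This list was the 1 list still called with an estimated correlation (camera adjusted p = 4.16e-10; adjusted p = 0.046 with an estimated correlation). This adjusted p was 0.265 with an estimated correlation when cKO replicate 3 was left out. The unadjusted fry p of the list was 5.4e-07, up, and 3.48e-06 without that library.

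The list of canonical Wnt targets was called up: 6 of 16 rose and none fell, 7 rose adjusted over the list alone, and 6 rose and 1 fell without cKO replicate 3. Tnfrsf19 rose by 1.35 (SE 0.206, edgeR adjusted p = 0.0156), Lef1, a nuclear effector of the pathway, by 2.05 (SE 0.381), Bmp4 by 2.52 (SE 0.402) and Notum, a Wnt deacylase, by 3.60 (SE 0.755). Nkd2 was the member that fell without cKO replicate 3 (-1.54). The list was called up (camera adjusted p = 0.0117; adjusted p = 0.322 with an estimated correlation), a call lost without cKO replicate 2 (0.0609) and without cKO replicate 3 (0.0641). Its median of 0.86 was 0.43 with limma-voom and 0.46 with log2(FPKM + 1) without a filter. The call of Tnfrsf19 was lost without control replicate 1 (adjusted p = 0.0846). Of 16 Hox genes, Hoxb7 and Hoxd3 (-1.13, SE 0.186, adjusted p = 0.0195) fell and Hoxd1 (1.71, SE 0.331) rose, the same numbers adjusted over the list alone; without cKO replicate 3, 4 fell and 1 rose. The Hox list was not called (camera adjusted p = 0.154), and Hoxd3 was not called without control replicate 2 (adjusted p = 0.12).

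Of 21 genes of the extracellular matrix and mesenchymal transition, 5 rose and none fell; adjusted over the list alone 6 rose, and without cKO replicate 3, 7 rose. Ccn2, a matricellular protein, rose from 81.9 ± 34.0 to 865 ± 131 CPM (log2 fold change 3.40, SE 0.334, edgeR adjusted p = 0.0057). Tagln (3.78, SE 0.478) and Acta2 (3.43, SE 0.553), both of the smooth muscle cytoskeleton, and the integrin gene Itga3 (0.57, SE 0.0972) rose. Cdh2, N-cadherin, was at 0 in all controls and at least 95.8-fold higher in cKO, with the floor taken over the group. The list median was 0.19 and its mean 1.44, so the call (camera adjusted p = 0.0117; adjusted p = 0.262 with an estimated correlation) rested on few members; it was lost without cKO replicate 2 (0.0612), with the stricter filter (0.0772, with a median of -0.03 over 13 genes) and with log2(FPKM + 0.1) (0.0503). With 1 library left out the median lay between 0.18 and 0.54, and with log2(FPKM + 1) without a filter it was 0.06. Tagln was not called without control replicate 1 (adjusted p = 0.0645).

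The list of interferon-stimulated genes was called up. Of 15 tested, 4 rose, none fell and 11 were not called; 14 had a positive fold change, and the median was 1.91 (camera adjusted p = 4.28e-06; adjusted p = 0.218 with an estimated correlation). The median was 1.06 over the 11 genes left by the stricter filter and 1.2 on the log2(FPKM + 1) scale (0.99 without a filter). Oas1a, a sensor of double-stranded RNA, rose from 2.10 ± 0.378 to 18.6 ± 4.48 CPM (edgeR adjusted p = 0.0147), and Irf7 (2.77, SE 0.544) and Cxcl10 (2.11, SE 0.453) rose as well. Adjusted over the list alone 5 rose, and without cKO replicate 3, 12 of 17 rose and 1 fell, Ifit2. Without control replicate 3 the adjusted p of Oas1a was 0.0863.

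**Figure D3:**
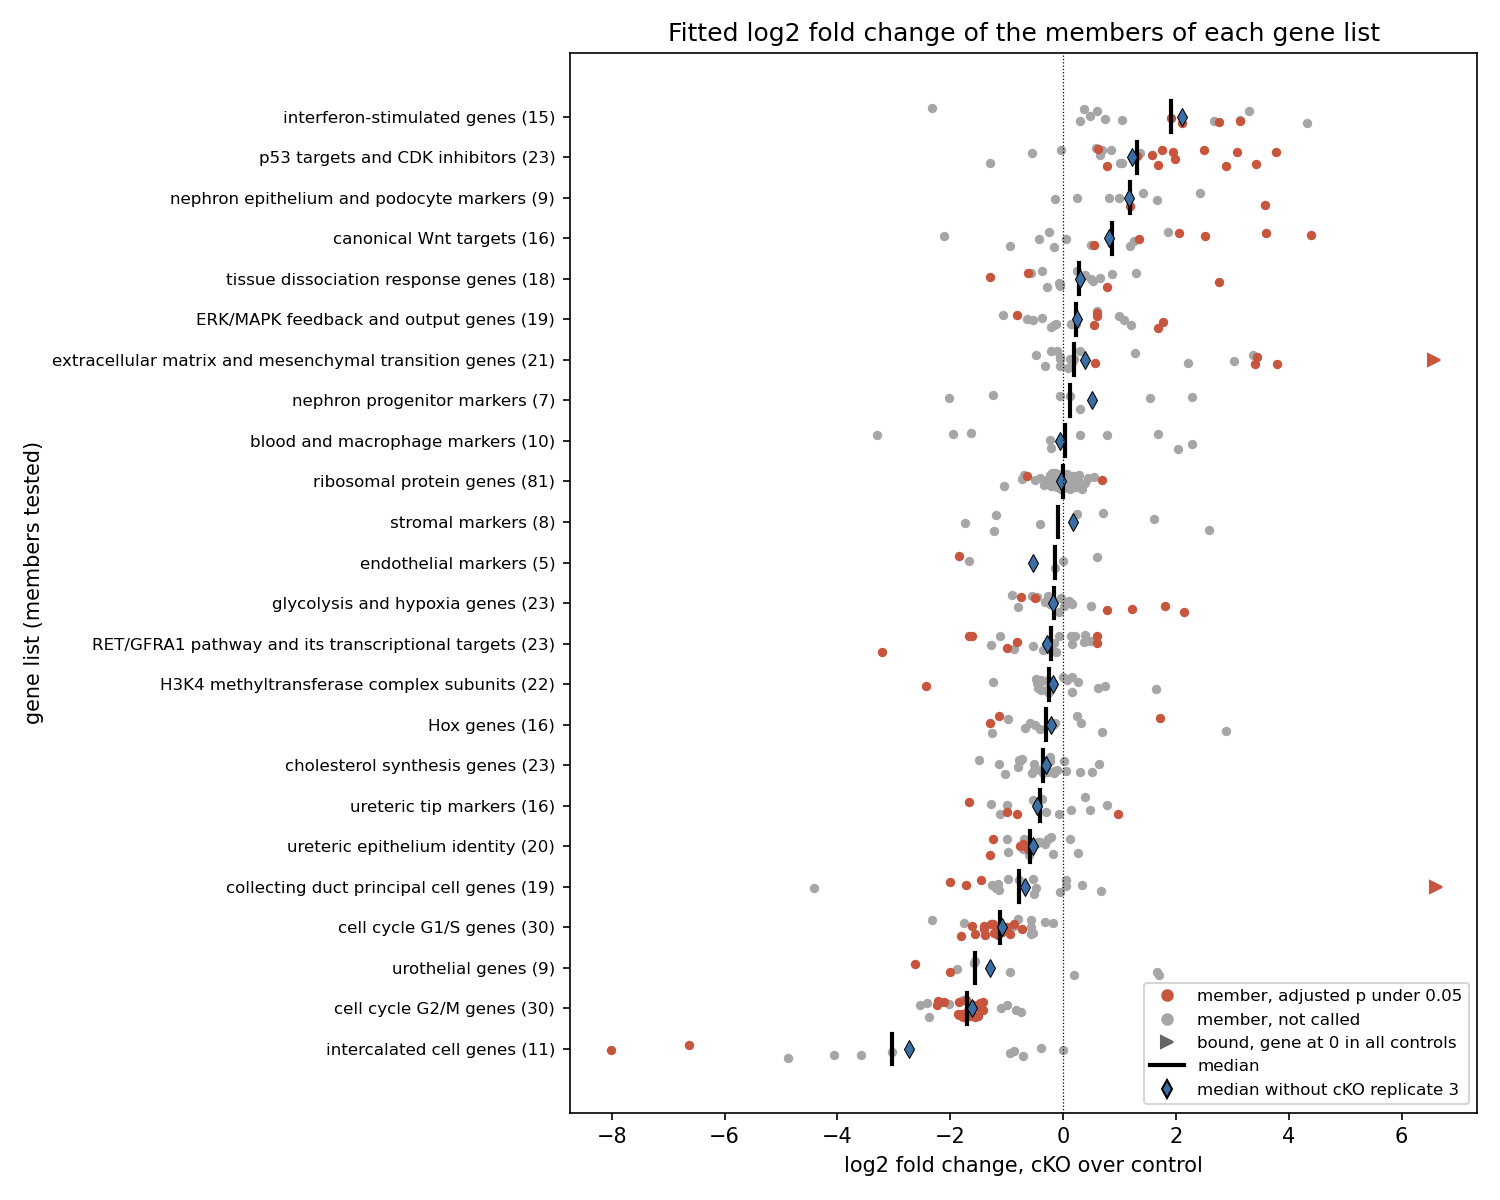
Fitted log2 fold change (cKO over control, horizontal axis) of each tested member of the gene lists with at least 5 tested members, whose number is in parentheses. Red points are members called with adjusted p under 0.05, grey points are not called, triangles are lower bounds of genes at 0 in all controls, black bars are medians and blue diamonds are medians without cKO replicate 3; cell cycle and intercalated cell genes lie left of 0 and p53 targets and interferon-stimulated genes mostly right of it.

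Metabolic lists were not called. Of 23 genes of glycolysis and hypoxia, 4 rose and 2 fell; adjusted over the list alone 5 rose and 3 fell, and without cKO replicate 3, 5 rose and 6 fell (camera adjusted p = 0.832). Adm, a hypoxia-induced peptide hormone, rose by 2.14 (SE 0.315, edgeR adjusted p = 0.0143), and the glycolytic enzyme genes Tpi1 (-0.75, SE 0.105, adjusted p = 0.0124) and Ldha (-0.50, SE 0.113) fell. The list median was -0.16 and its mean 0.06. Of 23 cholesterol synthesis genes, 0 were called with 6 libraries by edgeR, also adjusted over the list alone; Cyp51 had a log2 fold change of -0.51 (SE 0.136, adjusted p = 0.0737). The cholesterol list was not called (camera adjusted p = 0.0645); without cKO replicate 3, 8 members fell and it was called down (adjusted p = 0.0426; adjusted p = 0.754 with an estimated correlation). It was also called without control replicate 2 (0.0449), control replicate 3 (0.022) and cKO replicate 1 (0.0197), without a filter (0.0311), with limma-voom (0.0365) and with log2(FPKM + 1) with (0.0441) and without a filter (0.0254). With all 6 libraries its adjusted p = 0.578 with an estimated correlation. Of 3 tested germline genes, 0 were called. Sycp3 was 6.64 ± 1.44 CPM in controls and 9.23 ± 1.78 CPM in cKO, and Brdt was 4.73 ± 1.49 and 3.16 ± 2.74 CPM. Brdt had 45, 48 and 0 counts in cKO replicates 1, 2 and 3. Its log2 fold change of -0.58 was -0.0066 without cKO replicate 3. Without control replicate 3 the adjusted p was 0.0657 for Tpi1 and 0.0654 for Adm.

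Markers of other cell types were tested for cells that the sort could have carried along. Nephron epithelium and podocyte markers were called up (camera adjusted p = 0.0052; adjusted p = 0.218 with an estimated correlation; 0.0565 without control replicate 1). The call was also lost over all 17 listed markers without a filter (0.0601) and with log2(FPKM + 1) without a filter (0.091, with a median of 0.04). Of 9 tested, 2 rose, among them the Notch ligand gene Jag1 (1.19, SE 0.270, edgeR adjusted p = 0.0496). Adjusted over the list alone 4 rose, and without cKO replicate 3, 5 of 12 rose. Nephron progenitor markers (0 of 7 called, camera adjusted p = 0.676), stromal markers (0 of 8, 0.819) and blood and macrophage markers (0 of 10, 0.421) were not called. Their leading members were Cited1 (4.90 ± 1.32 and 14.3 ± 3.05 CPM), Meis2 (2.53 ± 1.49 and 15.2 ± 12.7 CPM) and Cd68 (3.98 ± 4.04 and 16.3 ± 2.48 CPM). With cKO replicate 3 left out, 1 of 7 nephron progenitor markers rose (Cited1, 1.35, adjusted p = 0.0123), 1 of 9 stromal markers (Meis2, 1.64, adjusted p = 0.0318) and 0 of 14 blood and macrophage markers. The median, mean and camera direction of the stromal and the blood lists differed in sign. The blood list was called up without control replicate 3 (adjusted p = 0.022); with all 6 libraries its adjusted p = 0.819 with an estimated correlation. Of 5 endothelial markers, Egfl7 fell (-1.85, SE 0.216, adjusted p = 0.00784), and the list was not called (camera adjusted p = 0.155). Egfl7 was not called without control replicate 3 (adjusted p = 0.0582), and with cKO replicate 3 left out 1 of 6 rose (Tek) and 1 fell. Of 4 neural crest and Schwann cell markers none was called with 6 libraries, and adjusted over the list alone 1 fell. With 5 members tested, this list was called down without control replicate 3 (camera adjusted p = 0.0149) and without cKO replicate 2 (0.0419); an estimated correlation was not tried in these tests.

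Of 18 genes induced by tissue dissociation, 2 rose and 2 fell (camera adjusted p = 0.155); adjusted over the list alone 3 rose and 2 fell, and without cKO replicate 3, 1 rose and 2 fell. The chaperone gene Hspa8 fell by 0.62 (SE 0.102, edgeR adjusted p = 0.0195), and Atf3, a stress-induced transcription factor, rose by 2.76 (SE 0.511), a call lost without 5 of the libraries in turn (0.101 without control replicate 2, 0.0819 without cKO replicate 3). Without control replicate 3 the list was called up (adjusted p = 0.022); with all 6 libraries its adjusted p = 0.714 with an estimated correlation. Hspa8 was not called without control replicate 3 (adjusted p = 0.0981). Of 81 ribosomal protein genes, Rps27l (0.69, SE 0.0954, adjusted p = 0.0115) rose and Rpl10 (-0.65, SE 0.118) fell, the same numbers adjusted over the list alone; without cKO replicate 3, 1 rose and 9 fell, and the list was not called (camera adjusted p = 0.819). Its median was -0.01 while camera gave it an upward direction. Rps27l was not called without control replicate 2 (adjusted p = 0.0729). Of 4 sex-linked genes, 3 fell, also adjusted over the list alone, and 4 fell without cKO replicate 3. Ddx3y had 953, 1044 and 392 counts in controls and 0 in each cKO library, at least 743-fold lower with the floor over the group (adjusted p = 0.00656). Uty was at least 319-fold and Kdm5d at least 189-fold lower.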

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

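Of the settings below, limma-voom with library weights, the test without the genes missing in cKO replicate 3 and the replicate block without that library were chosen after the data were seen. The counts of 459 genes that rose and 469 that fell moved by more than 1.5 times under several settings. They were 1111 and 1061 with DESeq2, 697 and 707 with limma on log2(FPKM + 1), 1594 and 1743 with library weights and 73 and 106 at an adjusted p under 0.01. At a change of at least 2-fold 264 genes fell. Leaving out 1 library gave between 62 and 1865 genes that rose and between 59 and 2032 that fell; the highest counts came without cKO replicate 3 and the lowest without control replicate 3. Other scalings, other filters, limma-voom, log2(FPKM + 0.1), log2(FPKM + 1) without a filter and the test without the missing genes stayed within 1.5 times. The spread between libraries moved too. The edgeR common dispersion was 0.256 with 6 libraries and 0.0357 without cKO replicate 3. That library had a limma-voom quality weight of 0.0685, against 1.38 to 1.94 in the others. Tests that left out another library kept cKO replicate 3. Beyond these values the cause of the moves was not tested. With the replicate number as a block (replicate block), 12 genes rose and 11 fell, and Ash2l had a log2 fold change of -2.50 (edgeR adjusted p = 0.0537, in a range over all its settings from 2.07e-14 to 0.0537). The block gave 1293 and 1601 once cKO replicate 3 was left out. Deviations from the group mean of libraries with the same number correlated at -0.022, 0.025 and -0.00145 across genes. Not every library correlated best with its own number. The cKO deviations were taken from a mean that includes cKO replicate 3, the library that stood apart. This check therefore cannot tell whether the numbers pair the samples. With the block the cholesterol list was called down (camera adjusted p = 0.0227); with the block without cKO replicate 3 it was called too (0.00615), the blood list was called up (0.00468) and the urothelial list was not called (0.285). With all 6 libraries, no block and an estimated correlation, the adjusted p = 0.578 for cholesterol and 0.819 for blood.

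The number of gene lists called was 11 and fell to 1 with an estimated correlation. For the p53 list the estimated correlation was -0.0332, below the preset 0.01. Its camera adjusted p still went from 4.16e-10 to 0.046. The drop therefore does not show that correlation between genes made the calls. Of the annotation terms, 22 were called, against 35 without a filter, 48 with log2(FPKM + 1) without a filter, 46 with library weights, 38 with the block without cKO replicate 3, 0 with an estimated correlation, and 9 to 35 with 1 library left out. For lists not called, the direction of the camera test turned under the settings that follow, in some of them with a median of unchanged sign; the cause was not tested. The stromal median of -0.0824 became 0.0740 with log2(FPKM + 1), 0.465 without the missing genes and 0.567 with the block without cKO replicate 3; with the block it was -0.866 and with library weights -0.0203. Its range with 1 library left out was -1.02 to 0.260. With 1 library left out the medians ranged from -0.192 to -0.0270 for glycolysis, -0.608 to 0.514 for nephron progenitors, -0.747 to 2.70 for blood and -0.0431 to 0.0277 for ribosomal protein genes. The ribosomal median was -0.0117 with library weights, -0.0213 without the missing genes and -0.0724 with the block without cKO replicate 3. The endothelial median was 0.308 without a filter. Cxcr4 ranged from -1.50 to 0.35 with 1 library left out, and Brdt was 0.28 with the block without cKO replicate 3. Of the other comparisons of named genes with 1 library left out, 253 kept direction and call, 101 lost the call and 9 gained it; under the remaining settings these were 854, 83 and 33. For gene lists they were 115, 12 and 7, and 316, 18 and 12. Depth limits the low genes: 3 counts in a library are 0.285 to 0.312 CPM.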

Other observations

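The lists of YAP/TEAD targets, SRF/MRTF targets and imprinted genes were made after the data were seen, because known members stood among the largest changes; the tests of a minimum count, of missing reads in cKO replicates 1 and 2 and of the p53 list without cKO replicate 3 were also chosen after the result was seen. Each new list was tested only on members whose values had not been looked at, without cKO replicate 3, against 10000 random lists matched on mean expression. The random lists draw genes and not libraries. The permutation p therefore takes no account of correlation between genes or of the spread between libraries. Members not looked at may also move together with those that prompted the list. The YAP/TEAD targets, genes driven by the Hippo pathway effector YAP, had 26 such members. Of these 7 rose and 0 fell by edgeR, and their median log2 fold change was 0.548, against a 95th percentile of 0.214 in matched lists (permutation p = 0.0002). Nuak2, a kinase gene, had a log2 fold change of 2.03 (SE 0.214, edgeR adjusted p = 1.79e-05), and Ajuba, a Hippo pathway adaptor, 0.70 (SE 0.159, adjusted p = 0.00677). With all 6 libraries 1 of the 25 members not looked at before rose and 0 fell.

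The SRF/MRTF targets, genes of the actin cytoskeleton, had 26 members not looked at before, of which 10 rose and 5 fell without cKO replicate 3. Their median was 0.295, against a 95th percentile of 0.155 (permutation p = 0.0023). Acta1, skeletal alpha-actin (5.39, SE 0.480, edgeR adjusted p = 0.000861), Myl9, a myosin light chain (2.12, SE 0.168), and Zyx, the focal adhesion protein zyxin (1.08, SE 0.149), rose, while the integrin gene Itga5 fell by 2.26 (SE 0.315). With 6 libraries 5 of 23 such members rose and 0 fell. The activity of YAP/TEAD and SRF/MRTF itself was not tested. Of 48 imprinted genes not looked at before, 33.3% were called without cKO replicate 3, against a median of 27.1% and a 95th percentile of 37.5% in matched lists (permutation p = 0.21), which leaves open whether imprinted genes changed more often than others. Sgce fell by 1.90 (SE 0.191) and Trappc9 rose (0.71, SE 0.131) without cKO replicate 3. With 6 libraries 2 of the 45 not looked at before rose and 0 fell. All genes named from these lists were chosen after their values were seen.

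The genes at 0 in cKO replicate 3 were weighed against 3 explanations. A minimum count applied to that library is argued against, since 322 genes have 1 to 3 counts there. The share at 0 was 544 times higher in the lowest than in the highest of 4 bins of expression, where 2 of 2935 genes were at 0. Too few starting molecules in that library would give such a gradient. Other causes could also leave low genes at 0 first, so the gradient does not tell them apart. A stronger effect of the knockout there stays open. Genes at 0 had a median log2 fold change in the other libraries that lay -0.279 from that of detected genes of the same expression. The 95% bootstrap interval was -0.332 to -0.206, resampling genes and not libraries. However, genes with lower levels in cKO also start from fewer molecules in that library.

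Cells of cKO replicates 1 and 2 had no reads of 4 Y-linked genes. Missing reads are argued against: 14 of the 12065 genes with over 10 counts in each control, 0.116%, were at 0 in both. The median log2 fold change of Eif2s3x, Ddx3x and Kdm5c, which escape X inactivation, was 0.478 without cKO replicate 3, consistent with a different sex makeup of the libraries. By edgeR without that library, Eif2s3x (adjusted p = 0.0155) and Ddx3x (0.0406) were called. Kdm5c (0.181) and Kdm6a (0.141), which also escapes, were not. How far sex makeup could contribute to the whole difference cannot be told apart from genotype, since the opposite makeup would rest on a single library, cKO replicate 3. Its own makeup is unclear, because it had reads of Eif2s3y but none of Ddx3y, Uty or Kdm5d. Its counts of Eif2s3x (349), Kdm5c (104) and Kdm6a (216) were below those of every control, and its 1598 counts of Ddx3x lay within the range of the controls. In cKO replicate 3, 84.3% of 3168 calls made without it had the same direction, against 54.0% of 2480 genes with an unadjusted edgeR p above 0.5. Both directions were taken against the same controls, and genes at 0 in cKO replicate 3 were left out. This can raise the shares, so they do not separate sex makeup from genotype.

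Without cKO replicate 3 the median of the p53 list, which rose, was 1.22 (95% bootstrap interval 0.760 to 1.93). Its camera adjusted p was 1.91e-06, but the adjusted p with an estimated correlation went from 0.046 to 0.265, so that call was not kept. The intervals given for this list resample its members and not the libraries, so they do not measure the spread between libraries. The size of the median argues against that library as the whole cause of the rise. With the dissociation score of each library as a covariate the median was 1.41 (0.607 to 1.83), against 1.31 before (0.785 to 1.95). The covariate takes a degree of freedom, and 6 members and 137 genes in all were then called, so a response to dissociation may still contribute. Loss of Ash2l, which the design names, was not tested apart from these.

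The 6 libraries can be divided into groups of 3 in 10 ways, too few for a share under 0.05. In 1 of the 10, the real one, 928 genes were called, and the highest number in any other was 0. For gene lists the real division gave 11 calls, again the most in 1 of the 10, and the highest other was 9.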
